A study of Mus musculus with 4 samples.

How the data were processed

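Gene expression was measured in mouse brain total RNA on Illumina bead arrays, 1 array per sample. Each array reads many short oligonucleotide probes, most of them designed for 1 transcript. Per the labels, RNA was extracted with Trizol and amplified to biotin-labelled complementary RNA, the mice were of a mixed 129J x C57BL/6 background, and 2 samples were Atm+/+ and 2 were Atm-/-. The genotype of each sample came from its genotype label and the replicate number from its title. The labels used here do not give the Atm allele, the age or sex of the mice, the part of the brain that was dissected, or whether the 2 samples of a genotype came from separate animals. The p-values of single probes therefore measure the spread between these samples, which may be technical. Fisher's exact and permutation tests used further below take genes or probes as their units instead.

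The values analysed were the log2 signals of 45281 probes that the authors deposited as their processed values. The software, background treatment and normalization behind them are not given in the sources used here, and the log base of 2 was inferred from the range of 4.47 to 16.1. When each array was sorted, values of equal rank differed by at most 0.0792 between arrays, as quantile normalization between arrays would leave them. The array medians lay between 5.546 and 5.549, and the values were not centred per gene. No further normalization was applied. Quantile normalization gives every array the same distribution, so a change of total RNA per cell, or a shift of most genes in 1 direction, cannot be seen in such values.

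A table of signals before normalization holds 8 more columns of per-sample values, 4 of signals and 4 of detection p-values. Their names match no label of a single sample, so they were not used. This changed the analysis planned before the data were examined, in which these signals were to be background-corrected and normalized with limma's neqc at an offset of 16, with probes chosen by detection p-value. The authors' processed values, meant for a comparison beside it, took that place. Detection was replaced by a background level drawn from the values, set without reference to genotype and before any test. The mode of all values was 5.054, the SD of the values under the mode was 0.195, and the level was placed 3 SD above the mode at 5.64. Probes above this level on at least 2 of the 4 arrays were tested, 22383 in all. On each array 47.0% to 47.1% of probes were above it. A probe at or below this level on both arrays of a genotype is called at background there. Its change is then given as at least N-fold, the mean of the brighter genotype against the background level, because a dim probe sets only a bound. A log2 change printed beside such a bound is the fitted value. The number of arrays limits the precision of every value.

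Gene symbols came from the platform annotation, in which 34885 probes have 1 symbol, 18 have several and 10378 have none. Symbols were looked up again through the gene identifiers in an NCBI RefSeq gene table, which matched 99.8% of them and changed 0. Of the tested probes, 19040 carried 1 symbol, and these stood for 12229 genes. Probes with several symbols were not named. No genome build goes with the values, so no coordinates are given, and the gene table served only for names and for which genes neighbour each other.

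Atm-/- was compared with Atm+/+ using lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 4 arrays, no covariate and no intensity trend. The fit had 2 residual degrees of freedom and 5.22 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the tested probes, and a probe was past the threshold at an adjusted p under 0.05. Changes are differences of mean log2 signal, Atm-/- minus Atm+/+, and each is followed by its moderated standard error (SE). Levels are means with the SD of 2 arrays. "Rose" and "fell" are used of probes past the threshold.

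A total of 46 gene lists was written before the data were examined, covering markers of brain regions and cell types, chromatin regulators, and signalling, stress and metabolic genes. The 45 lists with at least 5 tested genes were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. At that preset its p-value is set against the spread among genes and does not measure the spread between samples. Each gene was represented by its brightest tested probe, and p-values were adjusted over the 45 lists. Counts of members past the threshold are given over all probes and adjusted over the list alone. The same test with a correlation estimated from the 4 arrays stands beside it, and so does limma's fry, which asks whether the genes of a list move 1 way on balance without reference to other genes. The genes named were fixed by rule before the data were examined: Atm, Ezh2, the 10 largest rises and 10 largest falls among probes with a symbol past the threshold (predicted and numbered genes left out), and up to 4 members with the smallest p of each list described. Genes named outside this rule are said to be.

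The procedure was tested on simulated data, with the spread of each probe drawn from the variance model of the fit and equal in both genotypes. The real spread was unequal between the genotypes, as given below, and the simulation does not cover that. Among 22383 simulated probes with 50 changed at each size, 0% of 2-fold, 52% of 4-fold, 98% of 8-fold and 100% of 16-fold changes were recovered in the comparison of Atm-/- with Atm+/+, with 10 false calls. In a second simulation with 3000 changed probes, 4.12% of 1676 calls were false. Of the 45 lists, 0 unchanged ones were called at an adjusted p under 0.05 and a list that had been moved was found. The simulated probes varied independently, so this does not check the list test where genes of a list vary together.

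The alternatives tried were other filters on dim probes, other variance models, the replicate number as a block, leaving out each array in turn, other thresholds, an ordinary linear model, other set tests and other ways of taking 1 value per gene. Other background levels, centring of each array, array weights, 1 probe per gene in the count of probes and averaging of the Atm-/- arrays were added after seeing the data. The labels use the same replicate numbers in both genotypes, but nothing in them says that equal numbers share an animal, litter or day, so the samples were not treated as paired.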

Results

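Brain RNA of mice lacking Atm was compared with that of mice carrying it. Atm is the kinase that signals DNA double-strand breaks, and its loss in humans causes ataxia-telangiectasia, a disease with degeneration of the cerebellum. The series title places the arrays in a study of histone H3 methylation by EZH2, the catalytic subunit of Polycomb repressive complex 2. There were 4 arrays, 2 of Atm+/+ and 2 of Atm-/- brain, each with 45281 probes, of which 21290 to 21335 per array were above background. The contrast of the genotypes was the single comparison the design gave. Markers of the cortex, hippocampus and striatum, called forebrain markers here, were higher in Atm-/-. Markers of the cerebellum were lower, as was a list of thalamus, hypothalamus and brainstem, called the brainstem list here. That list mixes thalamus and hypothalamus, which are themselves parts of the forebrain, with the brainstem. Many of these markers moved from or to background, as described below. An effect of Atm loss on a gene therefore cannot be told apart from a difference in the brain regions sampled.

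Atm itself was lower in Atm-/- brain. Probe ILMN_1258206 fell by 2.36 ± 0.26 (SE, n = 2 per genotype) on the log2 scale, with a limma adjusted p of 0.00224, from 7.80 ± 0.06 (SD) in Atm+/+ to background on both Atm-/- arrays, which makes it at least 4.46-fold lower. Probe ILMN_2783896 also fell to background, by 1.35 ± 0.27 (adjusted p = 0.0205, at least 1.77-fold lower). That call was lost without Atm-/- replicate 1 or 2, at an adjusted p of up to 0.219. A further Atm probe, ILMN_2492491, for which the annotation gives no transcript, read 9.52 in Atm+/+ and 10.14 in Atm-/-, a difference of 0.61 ± 0.37 that did not pass the threshold (adjusted p = 0.308). The last Atm probe was too dim to be tested. Where these probes lie relative to the disrupted part of the gene is not known from the labels.

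**Figure D1:**
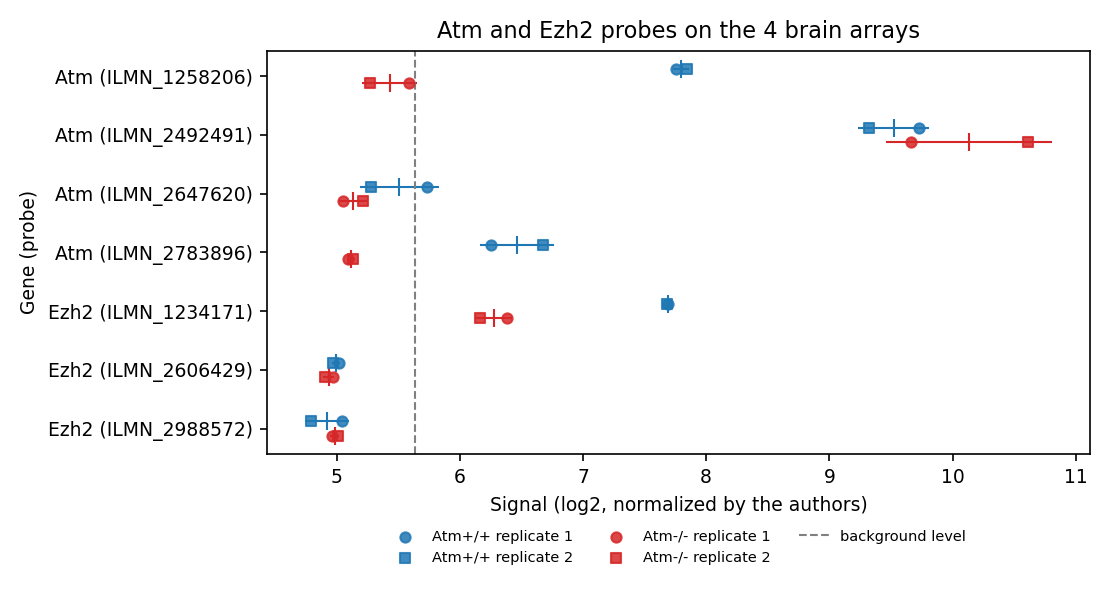
Log2 signal of every Atm and Ezh2 probe on each of the 4 arrays, with circles for replicate 1, squares for replicate 2, ticks and bars for the mean and SD of each genotype, and a dashed line at the background level of 5.64. Atm probe ILMN_1258206 reads 7.75 and 7.84 on the Atm+/+ arrays and lies below the line on both Atm-/- arrays, and Ezh2 probe ILMN_1234171 reads 7.69 and 7.68 against 6.38 and 6.17.

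Ezh2 was lower in Atm-/- brain as well. The brain-region markers described below moved in the same samples. Whether changes of Ezh2 and of the other Polycomb genes go with region or with genotype was not tested. The probe above background, ILMN_1234171, fell by 1.41 ± 0.25, from 7.69 to 6.27 (adjusted p = 0.0136). The call was lost without Atm-/- replicate 1 (adjusted p = 0.137) and without replicate 2 (adjusted p = 0.214), and the other Ezh2 probes were at background on all 4 arrays. Of the 10 tested genes of Polycomb repressive complex 2, Ezh2 fell and 0 rose. Rbbp7 at 0.77 ± 0.32, Suz12 at -0.27 ± 0.28 and Jarid2, at background on both Atm+/+ arrays, did not pass the threshold. The complex did not stand apart from other genes (camera adjusted p = 0.978), and its median of 0.12 and mean of -0.02 differed in sign. Of 16 genes of Polycomb repressive complex 1, Cbx6 rose by 1.38 and Cbx7 fell by 1.24, both calls being lost without either Atm-/- array (adjusted p 0.159 to 0.322). That list was not past the threshold either (camera adjusted p = 0.908), again with a median of 0.14 and a mean of -0.01 of opposite sign. Among 23 histone demethylases and H3K4 or H3K9 methyltransferases, the methyltransferase gene Kmt2c fell by 1.45 and the H3K27 demethylase gene Kdm6b rose by 1.04, with 1 fall and 0 rises adjusted over the list alone and a camera adjusted p of 0.864. Neither call held without either Atm-/- array (adjusted p 0.135 to 0.419).

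Across the array, 2919 of 22383 tested probes passed the threshold, 1562 higher and 1357 lower in Atm-/-, and stood for 2105 genes. Of these probes, 711 changed over 4-fold and 219 over 8-fold. At an adjusted p under 0.1 there were 4831 probes, and at an unadjusted p under 0.05 there were 6711. A set of 242 probes that passed was at background on both Atm+/+ arrays, and a further 220 on both Atm-/- arrays. Leaving out single arrays moved the count widely: 8320 without Atm+/+ replicate 1, 7529 without Atm+/+ replicate 2, 679 without Atm-/- replicate 1 and 666 without Atm-/- replicate 2. The spread was unequal between the genotypes. Over 2-fold differences separated the Atm+/+ arrays from each other at 2534 probes (11.3%) and the Atm-/- arrays at 165 (0.737%), against 4330 to 5026 between arrays of different genotype. Pearson's r across probes, which are not independent replicates, was 0.960 between the Atm+/+ arrays, 0.990 between the Atm-/- arrays and 0.911 to 0.922 between genotypes. The first principal component held 73.8% of the variance and parted the genotypes, and the next, with 20.9%, parted the Atm+/+ arrays from each other.

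The genes that rose most in Atm-/- brain included several known for their expression in the forebrain. Ddn, which encodes the postsynaptic protein dendrin, rose by 7.88 ± 0.27, from 6.68 ± 0.22 to 14.56 ± 0.15 (adjusted p = 5.77e-05). The activity-induced transcription factor gene Egr3 rose by 6.14 at ILMN_1227494, while its other tested probe, ILMN_2653543, was at background on both Atm+/+ arrays and did not pass (adjusted p = 0.110). Egr4 rose by 5.74 and Rprml by 5.22. The probes of the remaining 6 rises were at background on both Atm+/+ arrays. Icam5, the telencephalon-specific adhesion molecule telencephalin, was at least 38.6-fold higher, and Crym, a thyroid hormone-binding protein, at least 34.6-fold. The potassium channel gene Kcnj4 was at least 31.3-fold higher at ILMN_3005071 and at least 6.29-fold higher at its other probe. The cortical transcription factor gene Fezf2 was at least 31.1-fold higher at ILMN_2932692 and rose by 5.07 ± 0.27 at ILMN_2512430, which was above background on all 4 arrays. Tbr1, also a cortical transcription factor gene, was at least 28.9-fold higher. The homeobox gene Dlx1, of forebrain interneurons, was at least 26.6-fold higher. All 10 passed at adjusted p between 5.77e-05 and 0.000938.

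The genes that fell most included several known for the cerebellum, brainstem and spinal cord. Pcp2, a Purkinje cell protein, fell by 7.88 ± 0.25 from 12.89 ± 0.06 to background (adjusted p = 5.77e-05), at least 152-fold. Lhx1, a LIM homeobox gene of Purkinje cells, fell to background at both its probes, at least 39.6-fold and 17.5-fold. Hoxb5 and Hoxa5, homeobox genes of the hindbrain and spinal cord, fell at least 36.3-fold and 30.8-fold. En2, the engrailed gene of midbrain and cerebellum, fell by 5.86 ± 0.26. Dao, which encodes D-amino acid oxidase, was 29.8-fold lower at ILMN_2862633. Its Atm-/- values there, 5.696 and 5.641, lay just above the background level of 5.64, so this fold is close to a bound. At ILMN_2592844 Dao fell to background, at least 1.13-fold. In 2 further genes the probes differed. Tmem25 fell at least 192-fold at ILMN_2789294, while its other probes changed by -0.34 ± 0.26 and -0.74 ± 0.28 and did not pass the threshold. Epm2aip1 fell by 5.63 ± 0.30 at ILMN_2895177 and fell by 2.17 at ILMN_1256740, while its remaining probes read 0.69, -0.53 and -0.53 and did not pass. Lrrc57 fell at least 23.4-fold at its 1 tested probe, its other probe being too dim to test. All 20 of the largest changes stayed past the threshold whichever array was left out.

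**Figure D2:**
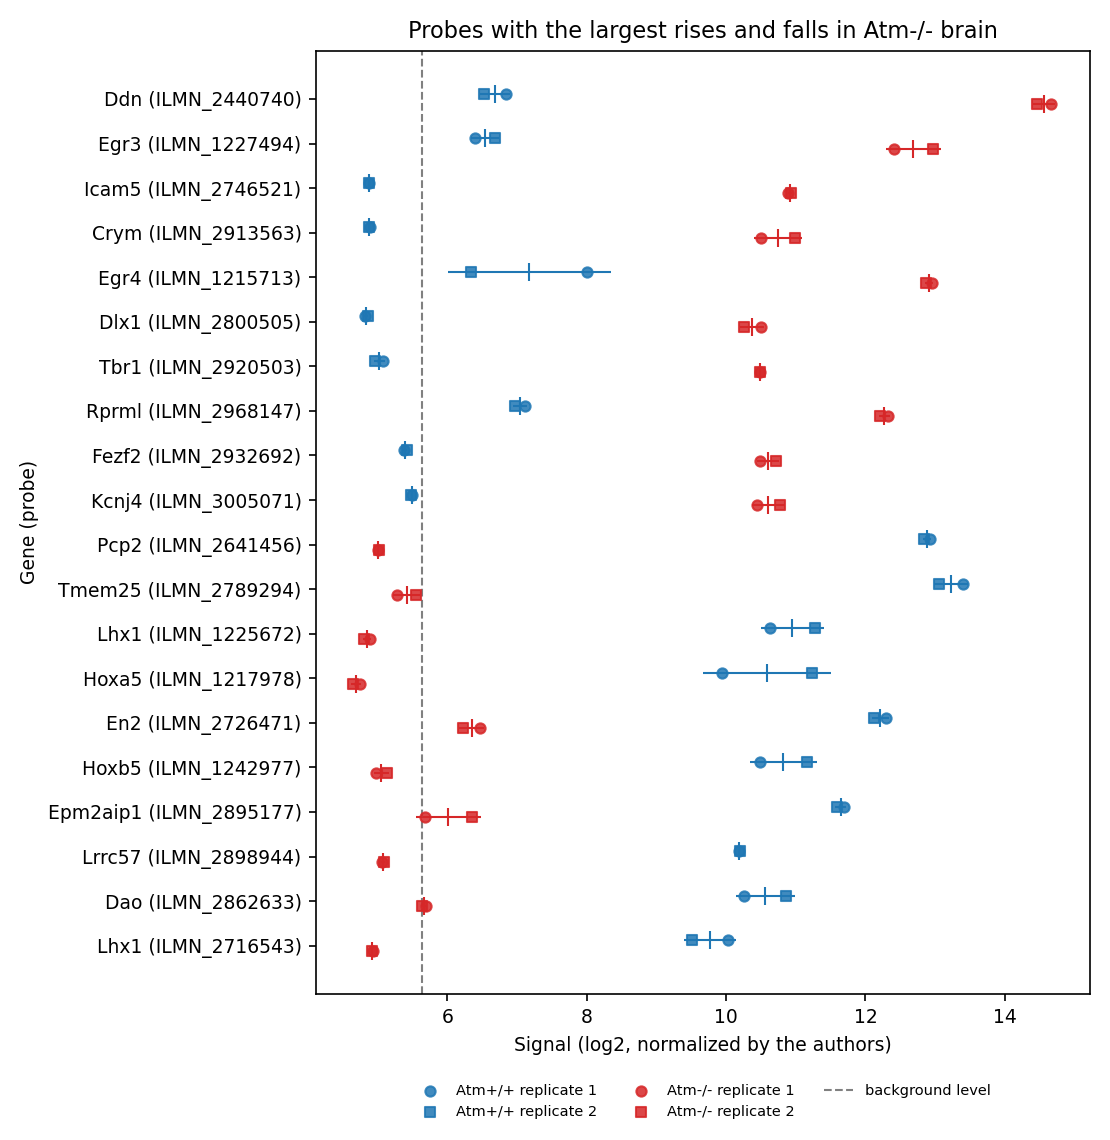
Log2 signal on each of the 4 arrays for the 10 largest rises and 10 largest falls, with symbols as circles for replicate 1 and squares for replicate 2, ticks and bars for the mean and SD of each genotype, and a dashed line at the background level of 5.64. The widest spread within a genotype is that of Egr4 in Atm+/+, with an SD of 1.17 around 7.17, while both Atm-/- values, 12.95 and 12.87, lie above both Atm+/+ values.

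Of the 45 gene lists, 20 passed the threshold with camera, 7 higher and 13 lower in Atm-/-. With an inter-gene correlation estimated from the 4 arrays 0 lists passed camera, 7 had an unadjusted p under 0.05 and the lowest adjusted p was 0.162. In that form camera rests on the 2 residual degrees of freedom and has little power. A miss in it, here or below, does not decide whether a list moved. Of the 20 lists, 14 passed fry, and fry also passed 4 that camera did not: glucocorticoid-responsive genes (fry adjusted p = 0.0372), histone deacetylases and MEF2 (0.0140), voltage-gated ion channels (0.0170) and genes near Atm (0.0480). In each of the 45 lists, leaving out an Atm-/- array never raised the number of members past the threshold and leaving out an Atm+/+ array never lowered it. The ranges given below for members past the threshold run over the 4 ways to leave out 1 array, with the lowest counts from leaving out Atm-/- replicate 1 or 2 and the highest from leaving out Atm+/+ replicate 1 or 2.

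**Figure D3:**
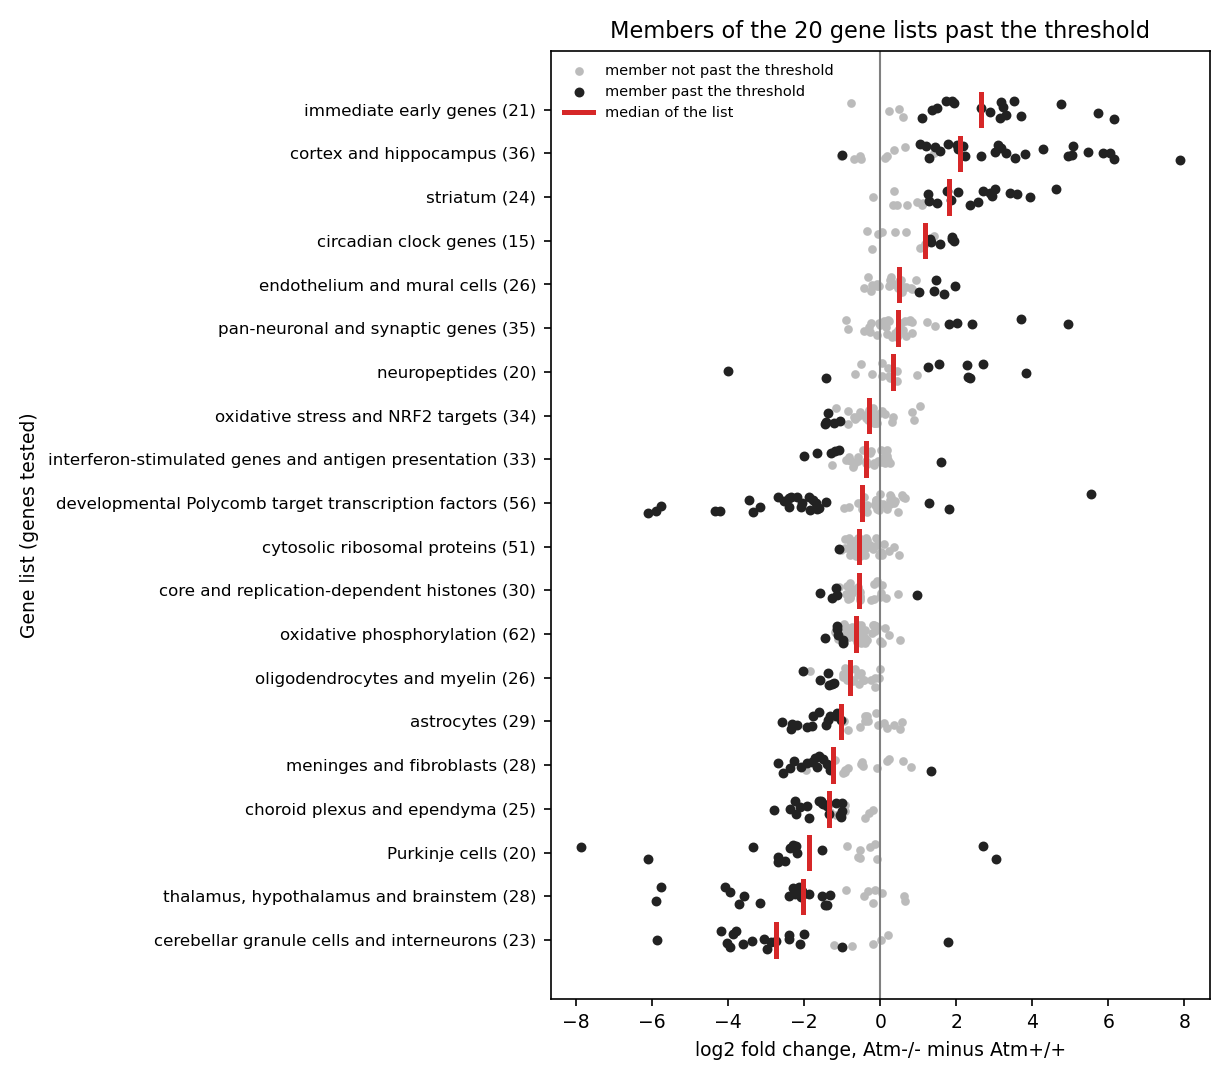
Log2 fold change (Atm-/- minus Atm+/+) of every tested member of the 20 gene lists past the threshold, 1 row per list, with dark points for members past the threshold, pale points for the others and a red bar at the median. Medians run from -2.74 for cerebellar granule cells and interneurons to 2.65 for immediate early genes.

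Markers of the cortex, hippocampus and striatum were higher in Atm-/- brain. Of 36 cortical and hippocampal genes, 26 rose and 1 fell (28 and 2 adjusted over the list alone), with a median of 2.11. Between 18 and 28 rose when 1 array was left out. The 4 of smallest p, Ddn, Icam5, Tbr1 and Crym, are described above. The list passed camera at an adjusted p of 4.57e-16, with an adjusted p of 0.162 with an estimated correlation. Of 24 striatal genes, 16 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.81, or 1.67 with dim genes at their bound, and 10 to 21 rose when 1 array was left out. The camera adjusted p was 1.01e-12, and the adjusted p was 0.162 with an estimated correlation. Arpp21 rose by 4.63 ± 0.32, Actn2 by 3.42 ± 0.26 and the calcium sensor gene Hpca by 2.89 ± 0.25. Drd1, the dopamine receptor of striatal projection neurons, was at background on both Atm+/+ arrays and at least 9.73-fold higher in Atm-/-. In all, 10 genes of these lists were at background on both Atm+/+ arrays and rose, and 0 were at background on both Atm-/- arrays and fell.

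Markers of the cerebellum were lower, and so was the mixed list of thalamus, hypothalamus and brainstem. Of 23 genes of cerebellar granule cells and interneurons, 17 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -2.74, and 14 to 18 fell when 1 array was left out. By camera its adjusted p was 8.30e-13, and the adjusted p was 0.162 with an estimated correlation. En2 led the list, followed by the transcription factor genes Tfap2b, which fell by 4.19, and Zic1, which fell by 3.96. Gabra6, a GABA receptor subunit of granule cells, fell to background, at least 8.47-fold. Of 20 Purkinje cell genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -1.87, or -1.64 with dim genes at their bound, and 9 to 13 fell when 1 array was left out. Its camera adjusted p was 1.39e-06, and the adjusted p was 0.194 with an estimated correlation. After Pcp2 and Lhx1, the calcium-binding protein gene Pvalb fell by 3.36, from 15.49 to 12.13, while Bcl11a, a transcription factor also of cortical neurons, rose by 3.05. Of 28 genes of thalamus, hypothalamus and brainstem, 20 fell and 0 rose (20 and 1 adjusted over the list alone), with a median of -2.04, or -1.96 with dim genes at their bound. Between 10 and 21 fell when 1 array was left out. This list passed camera at an adjusted p of 8.21e-12, with an adjusted p of 0.162 with an estimated correlation. Sncg fell by 4.09, and Slc6a2, the noradrenaline transporter, fell to background, at least 7.79-fold. Over these cerebellar and brainstem lists, 14 genes were at background on both Atm-/- arrays and fell, and 0 were at background on both Atm+/+ arrays and rose.

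Transcription factor genes known as developmental targets of Polycomb were lower in Atm-/- brain, and the brain-region markers above moved in the same samples. The list was written with 112 genes, of which 56 had a tested probe, so members dim in both genotypes are not counted. Of 56 tested members, 23 fell and 3 rose, with the same counts adjusted over the list alone, and the median was -0.47. Between 14 and 26 fell and between 1 and 5 rose when 1 array was left out. With camera the adjusted p was 5.33e-06, and the adjusted p was 0.342 with an estimated correlation. The 3 that rose were Dlx1, Dlx2 and Isl1, of which Dlx2 and Isl1 are named after their values were seen. Of 17 Hox genes, which pattern the hindbrain and spinal cord, 10 fell and 0 rose. Among the other 39 members, 13 fell and 3 rose. Lhx1, Hoxb5 and Hoxa5, also among the brain-region markers, were the falls of smallest p.

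Immediate early genes, which neurons transcribe within minutes of activity, were higher. Of 21 members, 17 rose and 0 fell, with the same counts adjusted over the list alone, and the median was 2.65. Between 11 and 18 rose when 1 array was left out. Against other genes the list had a camera adjusted p of 4.14e-14, and the adjusted p was 0.282 with an estimated correlation. Egr2 rose by 4.75 ± 0.29 and Egr1 by 3.51 ± 0.26, from 11.25 to 14.76. Fosb was at background on both Atm+/+ arrays and at least 6.41-fold higher in Atm-/-. Egr3 is also on the cortical list, which rose in the same samples. Of 15 circadian clock genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.18, a camera adjusted p of 0.000493 and an adjusted p of 0.282 with an estimated correlation. Between 0 and 9 rose when 1 array was left out. Ciart rose by 1.90, Per2 by 1.94, Per1 by 1.90 and Npas2 by 1.35, and each of these calls was lost without at least 1 of the Atm-/- arrays (highest adjusted p 0.0691 to 0.208). Of 21 glucocorticoid-responsive genes, 4 rose and 0 fell (10 and 4 adjusted over the list alone), among them Dusp1 by 1.94 and Fkbp5 by 1.21, with 0 to 11 rises when 1 array was left out. That list did not pass camera (adjusted p = 0.0608).

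Genes shared by most neurons were higher as a list with camera, in the same samples in which the forebrain markers rose. Of 35 pan-neuronal and synaptic genes, 5 rose and 0 fell, with the same counts adjusted over the list alone, and the median was 0.46. Camera gave an adjusted p of 0.00151, and the adjusted p was 0.469 with an estimated correlation. The list's call was lost without Atm+/+ replicate 1 (adjusted p = 0.140), and 3 to 13 members rose when 1 array was left out. Stx1a rose by 4.93, Camk2a, a kinase abundant in forebrain excitatory neurons, by 3.70, Homer2 by 2.41 and Camk2b by 2.02, the last with an adjusted p of 0.0596 without Atm-/- replicate 2. Of 20 neuropeptide genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.35, and 5 to 9 rose when 1 array was left out. The camera adjusted p was 0.0215, and the adjusted p was 0.563 with an estimated correlation. The call was lost without Atm+/+ replicate 1 (adjusted p = 0.0896) and without Atm-/- replicate 1 (adjusted p = 0.0658). Vip rose by 3.84 and Cck by 2.70, peptides of cortical neurons among others, and Cort, which encodes cortistatin, was at least 4.62-fold higher. Gal, which encodes galanin, fell from 9.81 to 5.82 (adjusted p = 0.000566).

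Lists of choroid plexus, meninges, astrocytes and oligodendrocytes were lower and that of endothelium higher, while those of microglia and of oligodendrocyte precursors did not pass (camera adjusted p of 0.768 and 0.368). The forebrain, cerebellar and brainstem markers moved in these same samples. Of 25 choroid plexus and ependymal genes, 18 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.34, a camera adjusted p of 1.13e-11 and an adjusted p of 0.162 with an estimated correlation. The log2 fold changes were -2.38 for Ecrg4, -2.79 for Col8a2, -2.25 for Dynlrb2 and -2.10 for Kl, and 5 to 23 members fell when 1 array was left out. Of 28 genes of meninges and fibroblasts, 13 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.25, or -1.16 with dim genes at their bound. The camera adjusted p was 4.54e-06, the adjusted p was 0.469 with an estimated correlation, and 2 to 20 fell when 1 array was left out. Ogn fell by 2.57 and Serping1 fell by 2.68. Of 29 astrocyte genes, 14 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -1.03, a camera adjusted p of 3.08e-06 and an adjusted p of 0.194 with an estimated correlation. The log2 fold changes were -2.58 for Agt, -2.31 for Sparc, -2.34 for S100b and -1.93 for the water channel gene Aqp4, and 3 to 19 fell when 1 array was left out, with Aqp4 at an adjusted p of 0.0661 without Atm-/- replicate 1. Of 26 oligodendrocyte and myelin genes, 6 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.79, a camera adjusted p of 3.32e-06 and an adjusted p of 0.317 with an estimated correlation. Ugt8a, of myelin lipid synthesis, fell by 2.02 (adjusted p = 0.0564 without Atm-/- replicate 1), and 0 to 15 members fell when 1 array was left out. Of 26 endothelial and mural genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.48, a camera adjusted p of 0.00419 and an adjusted p of 0.469 with an estimated correlation. Rgs5 rose by 1.98 (adjusted p = 0.0611 without Atm-/- replicate 2), and 0 to 14 members rose when 1 array was left out.

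Several lists passed camera although few of their members passed alone. The regional and glial markers moved in these same samples. Of 62 genes of oxidative phosphorylation, 6 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.64, or -0.62 with dim genes at their bound. Camera gave an adjusted p of 4.36e-08, the adjusted p was 0.342 with an estimated correlation, and 0 to 32 fell when 1 array was left out. Cox7b fell by 1.46 and Ndufb8 fell by 1.10. Of 51 cytosolic ribosomal protein genes, Rpl26 fell by 1.08 and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.55, a camera adjusted p of 6.60e-05 and an adjusted p of 0.469 with an estimated correlation. Between 0 and 26 fell when 1 array was left out. Of 30 histone genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), led by H4c8, which fell by 1.59. The median was -0.56, or -0.55 with dim genes at their bound, the camera adjusted p was 0.000955, the adjusted p was 0.563 with an estimated correlation, and 0 to 16 fell when 1 array was left out. Of 33 interferon-stimulated and antigen-presentation genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.38. The camera adjusted p was 0.0131, with an adjusted p of 0.342 with an estimated correlation and of 0.0865 without Atm+/+ replicate 1. H2-Ab1, an antigen-presenting class II gene, fell by 2.01 and Dhx58 fell by 1.65, while Tap2 rose by 1.60, and 0 to 15 fell when 1 array was left out. Of 34 oxidative stress genes and targets of the transcription factor NRF2, 5 fell and 0 rose (5 and 1 adjusted over the list alone), with a median of -0.30. The camera adjusted p was 0.0184, the adjusted p was 0.480 with an estimated correlation, and the call was lost without either Atm-/- array (adjusted p of 0.0663 and 0.0525). The glutathione peroxidase genes Gpx4 and Gpx3 had log2 fold changes of -1.42 and -1.38, and 0 to 11 fell when 1 array was left out. Each gene named here lost its call without at least 1 of the Atm-/- arrays (highest adjusted p 0.0703 to 0.434).

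Genes of the DNA damage response, in which Atm acts, did not pass camera as lists. Of 34 genes of damage signalling and repair, Fancd2 rose by 2.38 ± 0.28 and Polb, a base-excision repair polymerase, fell by 1.07 ± 0.25 (1 and 0 adjusted over the list alone), with a median of 0.10, a camera adjusted p of 0.768, and 1 to 5 rises and 0 to 6 falls when 1 array was left out. Chek2, a kinase downstream of Atm, did not pass at -0.89 ± 0.27. Of 29 targets of p53, 2 rose and 2 fell (4 and 3 adjusted over the list alone), with a median of 0.06, a camera adjusted p of 0.702, and 1 to 8 rises and 0 to 4 falls when 1 array was left out. Plk2 rose by 2.71 and Apaf1 by 1.33, while Rps27l fell by 1.84 and Phlda3 fell by 1.22. Of 19 apoptosis genes, Hrk rose to at least 4.30-fold and Birc2 fell by 0.99 (1 and 1 adjusted over the list alone), with a camera adjusted p of 0.702 and ranges of 0 to 4 rises and 0 to 5 falls. Of 28 genes of the G1/S transition and DNA replication, 2 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.959; 1 to 8 rises and 0 to 6 falls when 1 array was left out). E2f1 rose by 2.49 and Ccnd2 by 1.20, while Ccne2 fell by 1.70 and Mcm2 fell by 1.28. That list's median of -0.09 and mean of 0.04 differed in sign. Of 16 G2/M genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.525; 0 to 6 rises and 0 to 3 falls when 1 array was left out). Without at least 1 of the Atm-/- arrays the calls of Polb, Apaf1, Rps27l, Phlda3, Hrk, Birc2, Ccnd2, Ccne2 and Mcm2 were lost (highest adjusted p 0.0512 to 0.431). A list missing the threshold does not show that its genes are alike in both genotypes. The brain-region markers moved in these same samples, so an effect of Atm on these genes was not told apart from one of region.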

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

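Background levels at 2 and 6 SD, array centring, array weights, 1 probe per gene and averaging of the Atm-/- arrays were chosen after seeing the data; the other settings were fixed before. All 2919 probes past the threshold had both Atm-/- arrays on the same side of both Atm+/+ arrays. Leaving out an array could thus not reverse them, so the direction they kept in every setting that tested them is no check. The number of calls is what moved. The settings that start from signals before normalization (quantile normalization without normexp, normexp with median scaling, an offset of 50) were not run, because the names of those columns match no sample. With the authors' values alone, the effect of background correction and normalization remains unmeasured, and 22898 probes at background on 3 or more arrays were not tested. In simulation, with equal spread in both genotypes, 0% of 2-fold and 52% of 4-fold changes were recovered. Many changes of 2-fold may thus be missed, although some of about that size passed, such as the fall of Birc2 at -0.99.

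Leaving out 1 array gave between 666 and 8320 probes, with 387 to 4174 higher and 256 to 4146 lower. The low counts came without an Atm-/- array, where the fit takes its residual spread from the Atm+/+ pair alone and the lone sample is assumed to vary like that pair, and the high ones without an Atm+/+ array, where it rests on the closer Atm-/- pair. Averaging the Atm-/- arrays to 1 sample gave 645 probes, 389 higher and 256 lower. At an adjusted p under 0.1 there were 4831, 2472 higher and 2359 lower. An ordinary linear model without variance moderation called 0 probes, 0 higher and 0 lower, with 4484 at an unadjusted p under 0.05. With 1 probe per gene, 12229 being tested, there were 2000, 1037 of them higher. The replicate block gave 4574 probes, 2378 higher and 2196 lower, and an adjusted p of 0.0839 for the list of oxidative stress and NRF2 targets. Differences between replicate numbers correlated at 0.0590 across the genotypes, so the numbers were not taken to pair the samples. The other filters and variance models gave 2360 to 3449 probes.

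The fall of Atm probe ILMN_1258206 was -2.36 in the ordinary linear model, where it missed the threshold (adjusted p = 0.150) that it passed in every other setting that tested it. Probe ILMN_2783896 ranged from -1.56 to -1.14 when 1 array was left out and missed the threshold without either Atm-/- array (-1.33 and -1.37, adjusted p of up to 0.219), at -1.35 with the averaged arrays (adjusted p = 0.220) and at -1.35 in the ordinary linear model (adjusted p = 0.197). The 20 largest changes kept their calls in each setting that tested them apart from the ordinary linear model. Of 146 named probes past the threshold, 65 kept their calls whichever array was left out and 81 did not, the largest of these with a log2 change of 2.27 in size. Reversed signs occurred in genes that had not passed: Eif2s3y at -0.30 and Uty at -0.06 without Atm+/+ replicate 2, and Eif2s3y at -0.07 and Uty at -0.12 without Atm-/- replicate 2, with ranges over the left-out arrays of -0.30 to 0.48 for Eif2s3y and -0.12 to 0.22 for Uty. The highest correlation between genotypes rose to 0.954 when every probe was used.

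With the inter-gene correlation estimated, 0 lists passed, 0 higher and 0 lower, with 7 at an unadjusted p under 0.05. With 2 residual degrees of freedom that test has little power, so its misses do not decide whether a list moved. The adjusted p was 0.162 for cortex and hippocampus, cerebellar granule cells, striatum, brainstem and choroid plexus, 0.194 for Purkinje cells and astrocytes, 0.282 for immediate early and circadian genes, 0.317 for oligodendrocytes, 0.342 for oxidative phosphorylation, Polycomb targets and interferon genes, 0.469 for meninges, ribosomal proteins, pan-neuronal genes and endothelium, 0.480 for NRF2 targets, and 0.563 for histones and neuropeptides. With fry the adjusted p was 0.0687 for meninges, endothelium and neuropeptides, 0.0556 for ribosomal proteins, 0.0815 for pan-neuronal genes and 0.144 for histones. Averaged Atm-/- arrays gave NRF2 targets 0.0559. Lists that lost their call without 1 array were pan-neuronal genes (6.03e-06 to 0.140 over the 4 arrays left out), interferon genes (0.00725 to 0.0865), neuropeptides (0.00301 to 0.0896) and NRF2 targets (0.0332 to 0.0663). Where no reason is given above, the cause was not tested.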

Other observations

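The tests of explanations in this part were all chosen only after the results they bear on had been seen, as was the assignment of Polycomb targets to regions. Alg9, Atp2c1, Il20rb and Xist lie outside the naming rule and were chosen after their values were seen.

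Of 45 genes listed under voltage-gated ion channels, 6 rose and 6 fell (11 and 7 adjusted over the list alone). There were 5 to 12 rises and 0 to 9 falls when 1 array was left out. The list also holds an inward rectifier gene, Kcnj4, and genes of channel-associated proteins, Cacng3 and Kcnip2. The list did not pass camera (adjusted p = 0.355) and passed fry (adjusted p = 0.0170). In this part too the lowest counts came without an Atm-/- array and the highest without an Atm+/+ array. Besides Kcnj4, the rises of smallest p were Cacng3 at 3.07 ± 0.25, Kcnip2 at 2.97 ± 0.25 and the T-type calcium channel gene Cacna1h at 2.20 ± 0.25. Of 22 glutamate and GABA receptor genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone, 0 to 9 rises and 1 to 4 falls when 1 array was left out, camera adjusted p = 0.239). The metabotropic receptor gene Grm4 fell by 2.74, while Grin2b rose by 1.81, Gria2 by 1.61 and Gabra3 by 1.40, these 3 calls being lost without either Atm-/- array (adjusted p of up to 0.217). The neuronal transcription factor gene Mef2c rose by 3.76 ± 0.26, from 9.27 to 13.03, with 2 further rises, Sirt7 and Hdac8, and 0 falls among 19 histone deacetylase and MEF2 genes (3 and 0 adjusted over the list alone, 1 to 6 rises and 0 to 3 falls when 1 array was left out). Sirt7 and Hdac8 lost their calls without either Atm-/- array (adjusted p of up to 0.425), and the list did not pass camera (adjusted p = 0.165) but passed fry (adjusted p = 0.0140). Of 11 skeletal muscle genes, 4 rose and 1 fell, with the same counts adjusted over the list alone and 3 to 5 rises when 1 array was left out (camera adjusted p = 0.168). Tcap was at least 10.2-fold higher, Tnnc1 rose by 2.74 and the actin gene Acta1 by 3.43 ± 0.60.

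Microglial genes moved both ways: 5 fell and 1 rose of 29 (7 and 4 adjusted over the list alone, 1 to 7 falls and 0 to 11 rises when 1 array was left out, camera adjusted p = 0.768), with a median of 0.41 and a mean of -0.05 of opposite sign. Fcer1g fell to background, at least 6.25-fold, and Mrc1, a marker of border macrophages, fell by 2.27 (adjusted p = 0.0807 without Atm-/- replicate 1). Among 16 inflammation and complement genes Serpina3n rose by 3.49 and Serping1 fell by 2.68 (camera adjusted p = 0.978, 1 to 6 rises and 1 to 3 falls when 1 array was left out). Y-linked Eif2s3y was above background on all 4 arrays at both its probes, and 3 of 4 Xist probes were at background on all 4, the other being above it on Atm-/- replicate 1.

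The remaining lists did not pass camera either, and genes near Atm alone among them passed fry (adjusted p = 0.0480). Across them 0 to 8 members of a list rose and 0 to 12 fell when 1 array was left out. Members that rose and fell numbered 1 and 7 of 40 genes near Atm (2 and 10 adjusted over the list alone, camera adjusted p = 0.355), 1 and 1 of 19 glycolysis genes (0.215), 1 and 1 of 5 pituitary and pineal genes (0.355), 0 and 0 of 19 cholesterol synthesis genes (0.361), 2 and 2 of 16 genes of oligodendrocyte precursors (0.368), 2 and 0 of 27 ubiquitin-proteasome genes (0.702) and 1 and 1 of 35 genes of the unfolded protein response and heat shock (0.702). They numbered 3 and 2 of 24 genes of insulin and mTOR signalling (0.768), 1 and 0 of 10 blood cell genes (0.768) and 0 and 1 of 33 genes of autophagy and lysosome (0.978).

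The markers of forebrain and of cerebellum and brainstem moved in opposite directions, many from or to background. A loss of cerebellar neurons alone would raise all other regions alike, yet the median of the cortical list exceeded that of the brainstem list by 4.14 on the log2 scale (95% bootstrap interval 3.02 to 5.26). The genes of each list were resampled as if independent, so the interval does not measure the spread between samples. Zic1 is on both the brainstem and the cerebellar granule cell list, so cerebellar loss could itself lower part of the brainstem list. A swap of 1 array between genotypes is argued against too, since the highest correlation between genotypes, 0.922, lay below the lowest within a genotype, 0.960. Different brain regions in the tissue of the 2 genotypes remain a candidate explanation: 10 cortical or striatal genes rose from background on both Atm+/+ arrays, and 14 cerebellar or brainstem genes fell to background on both Atm-/- arrays, with 0 the other way in each set. The bound of 10 genes for this test was met exactly and had been set with the values known. The design ties any such difference in dissection to genotype, so an effect of Atm within a region was not tested and stays open, as does the dissection itself. The 4 arrays have 3 splits into 2 and 2, too few for a share under 0.05. With limma 1 of 3, the real one, gave 2919 probes, and the highest other gave 0, with 80 and 54 at an unadjusted p under 0.05 in the other splits.

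Of 56 tested developmental Polycomb targets 23 fell and 3 rose beside a lower Ezh2 signal, whereas loss of repression would raise them. Members dim in both genotypes were not tested. The list was lower with camera and did not pass camera with an estimated correlation (adjusted p = 0.342), a test with little power here. A lowering of the whole list is not excluded: 3 members rose, but 1 to 5 did when 1 array was left out (1 without either Atm-/- array), and 1 rise, that of Dlx1, stood whichever array was left out. The region in which each factor is known to be expressed is another candidate explanation. Of members assigned behind the forebrain 18 fell and 0 rose, of those assigned to the forebrain 3 rose and 0 fell, and of 23 not assigned 5 fell and 0 rose. As the regions were assigned with these directions known, Fisher's exact test on the assigned members (2-sided, p = 0.000752) does not bear on it, and region, a lowering of the list and a change in Polycomb repression all stay open.

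In 18 of 4391 genes with several probes, Atm and Tmem25 among them, 1 probe at background in 1 genotype differed by over 2 on the log2 scale as measured, while another, above background on all 4 arrays, changed by less than 0.75 and did not pass (for 7 of the 18 the bound on the fold is under 4). Strain differences under the probes, carried beside the disrupted Atm locus on a mixed background, may contribute: leaving out Atm, 2 of 38 genes within 100 genes of Atm (Alg9 and Tmem25) were of this kind against 14 of 4324 elsewhere (Fisher's exact test, 2-sided, p = 0.00821). That rests on 2 genes, with p by the same Fisher's exact test of 0.120 without Tmem25 and 0.0204 to 0.0641 with windows of 20, 50, 200 or 400 genes, and the share of all probes past the threshold near Atm, 26 of 191 (13.6%), was close to the 13.3% elsewhere (Fisher's exact test, 2-sided, p = 0.831). For inherited blocks in other places, 2 neighbouring pairs were seen against a mean of 0.597 in random draws (permutation p = 0.109, 1-sided, or 0.0269 with Atm counted). As 1 of these pairs, Atp2c1 and Il20rb, lies 405 and 370 genes from Atm on its chromosome, such blocks stay open, and other transcript forms were not tested.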
